A study of Mus musculus with 2 samples.

How the data were processed

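H3K27me3, the trimethyl mark on lysine 27 of histone H3 that Polycomb repressive complex 2 deposits at silenced chromatin, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq). The cells were primary mouse regulatory T cells described by the labels as inflammation-experienced. They came from an adult male, aged 6 months, carrying Foxp3CreERT2 and Rosa26YFP. The labels give both libraries the same biosample, the same donor and biological replicate number 1, and they number them technical replicates 1 and 2. Both libraries were therefore treated as 1 group holding 1 biological sample, and are called library 1 and library 2 after those numbers. No input or control-antibody library was analysed here.

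The deposited values are counts: each table gives 1 whole number for each of 33643 numbered rows, with no scaling applied by the authors that the values show. Per the readmes deposited with the samples, each table is a quantification of type "enrichment" made from the alignment of that library to mm10 and from 1 further file that is the same for both libraries. That further file was not used here. Whether a count is of single reads or of fragments is not stated, and counts are called reads below. The tables hold a row number and a count only, so a row is called a region below without its position, width or gene being known. The aligner, the counting tool, and any filter on duplicate or ambiguously mapped reads are not given in the sources used here. Because widths are unknown, a high count may reflect a wide region as well as a dense mark, and the counts are not relative to any control. The split of a single row's reads between the libraries does not depend on its width, but it still has no control. Agreement and overlap across rows can depend on widths, since a wide region may collect more reads in both libraries.

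The planned work was fixed before the data were examined. It included 12 gene lists (developmental Polycomb targets, regulatory T cell genes, effector cytokines and markers of other blood lineages among them), the location of regions relative to genes, and their widths. These parts were not run, because matching row numbers to mm10 positions would have been a guess. The rule for naming items was kept as far as it applied: the 15 regions with the highest mean count, the lowest regions, and up to 3 regions per library past the threshold for a difference. Regions are identified by row number, and only the regions that passed that threshold are printed by number. Row numbers are also printed for the limits of runs of rows.

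Regions with reads were counted per library, with exact Clopper-Pearson 95% intervals for shares. A region was called high at 4 times the median count of its library or more, a rule added after the data were seen. Agreement was measured across regions by Pearson's r on log2(count + 1) and by Spearman's rho, with no p-value, since regions of 1 sample are not independent replicates. To show what counting error alone gives, each region's reads were dealt out between the libraries at the overall share of library 1, in 200 simulations. The split of each region's reads was compared with that share by a two-sided exact binomial test with Benjamini-Hochberg adjustment over all regions with a read. The variance of the splits was set against its binomial value overall and in classes of total count, with 1000 simulated splits per class. Shares of library 1 were compared between classes by Fisher's exact test with Benjamini-Hochberg adjustment over 4 comparisons. These classes and comparisons were not in the planned work, so their p-values are not those of planned tests. All of these tests treat reads as independent and compare the libraries, not biological replicates. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only.

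The order of the rows was examined after the data were seen. Runs of rows with 8 or fewer reads in both libraries together were found as highest-scoring segments, scored against 1000 shuffles of the rows, and runs of at least 100 rows were kept. Ratios of mean counts have bootstrap intervals from 1000 resamples of blocks of 20 adjacent rows. Correlations between neighbouring rows were set against 200 shuffles.

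The binomial test was tested on simulated data built from the real regions and library totals, in which 200 regions differed between the libraries. In each, 1 library was multiplied and the other divided by the square root of the fold. This raises the expected total of a changed region, so the calls below overstate the reach of the test at the real counts. With changed regions drawn from those with 20 or more reads in all, it called 6 of 200 at a 2-fold change among 33382 regions tested, 112 of 200 at 4-fold among 33375, and 195 of 200 at 8-fold among 33383. Drawn from all regions with reads, it called 2, 29 and 89 of 200 at the same folds. Calls among unchanged regions numbered 0 to 6 per simulation. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, which supplied scaling factors by the trimmed mean of M-values (TMM) as an alternative. Other alternatives were the pseudocount (0.1 and 5), a filter removing about the lowest 25% of regions, a stricter adjusted p of 0.01, and the upper 50% of the regions.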

Results

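The data comprised 2 technical ChIP-seq libraries for H3K27me3 from 1 biological sample of inflammation-experienced regulatory T cells. Regulatory T cells are the CD4 T cells, defined by the transcription factor Foxp3, that restrain immune responses. Both libraries were counted over the same 33643 numbered regions of the mouse genome. Library 1 held 300121 reads in these regions and library 2 held 275229, a ratio of 1.09. The median count per region was 6 in each library, with quartiles of 4 and 10 in library 1 and of 4 and 9 in library 2. With 1 group and 1 biological sample, the design contains no contrast between conditions. The comparison it implies is how far the H3K27me3 profile of the same cells agreed between the libraries.

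H3K27me3 reads were unevenly spread: most regions carried few reads and a small set carried many. In library 1, 1831 regions (5.44%, 95% interval 5.20 to 5.69) reached at least 24 reads, 4 times the median. In library 2 the same threshold was reached by 1489 regions (4.43%, 95% interval 4.21 to 4.65). These sets shared 1315 regions, against 81.0 for independent lists of those sizes. Another 516 regions reached the threshold in library 1 alone and 174 in library 2 alone. The threshold was the same number of reads in both libraries although library 1 held more reads in the regions, a total called depth here. This larger total made up part of the imbalance. Reads outside the regions are not known, so deeper sequencing and a larger share of reads in regions cannot be told apart. With library 1 thinned to the depth of library 2, on average over 100 draws, 1599 regions (4.75%) were high in library 1, with 353 in library 1 alone and 243 in library 2 alone. Nearly all high regions were above the ordinary level in the other library too. Of the 1831 regions high in library 1, 1830 exceeded the median of library 2, where their median count was 31. All 1489 regions high in library 2 exceeded the median of library 1, where their median count was 40.

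The concentration of the reads was measured with the top regions chosen in one library and the reads counted in the other. The top 1% of regions in library 2 (336 regions) held 9.02% of the reads of library 1. The top 1% in library 1 held 8.72% of the reads of library 2. For the top 10% (3364 regions) the corresponding shares were 34.3% and 33.2%. The libraries shared 272 of their top 336 regions, where independent lists would share 3.36. They shared 2512 of their top 3364, where independent lists would share 336.4.

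At the other end of the range, 527 regions had no read in library 1 (1.57%, 95% interval 1.44 to 1.70) and 566 had none in library 2 (1.68%, 95% interval 1.55 to 1.83). No read was found in either library for 57 regions. A count of 0 allows a level of up to 3 reads, against a median of 6 in each library, so absence of the mark was not detectable at this depth. In all, 32607 regions (96.9%, 95% interval 96.7 to 97.1) had at least 1 read in both libraries. Independent lists of these sizes would share 32559. Nearly every region had a read in each library, so the overlap could hardly lie far from that number. The overlap was above it, so more regions were empty in both libraries than independent lists would give.

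Across the 33643 regions, counts on the log2(count + 1) scale correlated between the libraries with Pearson's r = 0.708 and Spearman's rho = 0.659. Unknown widths may add to this agreement and to the shared lists above, since a wide region may collect more reads in both libraries. Counting error alone, simulated from the pooled counts, gave r from 0.707 to 0.716 and rho from 0.656 to 0.666 (95% of 200 simulations), so both values lay within the range of sampling noise. On the scale of raw counts Pearson's r was 0.924, under the simulated range of 0.933 to 0.936. The variance of the split between libraries was 1.016 times its binomial value over 33586 regions with a read, just inside the simulated range of 0.986 to 1.016. The same quantity as a chi-square was 34118 on 33585 degrees of freedom (upper-tail p = 0.020 from the chi-square approximation). This is a one-sided reading that does not use the simulations, so it is not a second piece of evidence. The departure from pure counting error was thus small, and its place in the range of counts is described next.

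**Figure D1:**
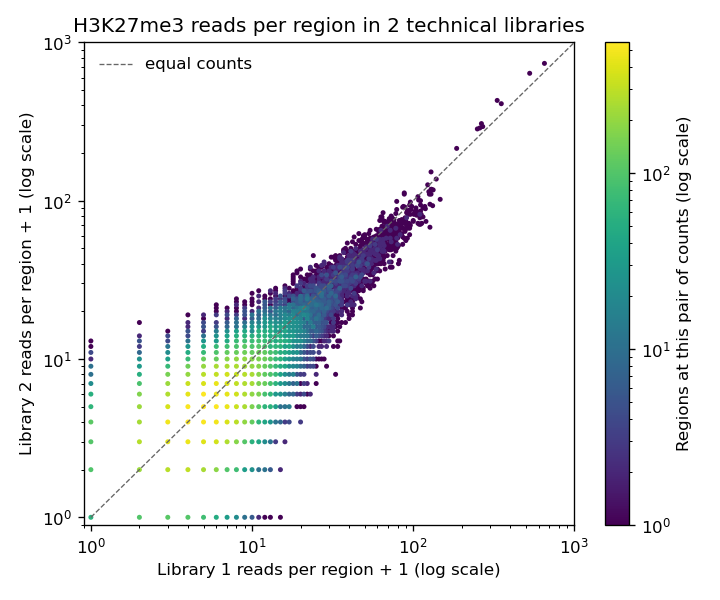
Reads per region in library 1 (x axis) against library 2 (y axis), both as count + 1 on log scales. Each point is a pair of counts, coloured by how many of the 33643 regions have it, and the dashed line marks equal counts; the scatter narrows as counts rise, and the 8 regions with 400 or more reads in all lie above the line.

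Library 1 took a larger part of the reads in regions of 50 to 199 reads than in regions of 5 to 9 reads. Over all regions it held 52.2% of the reads. Its share was 51.1% (95% interval 50.7 to 51.5) in the 9299 regions with 5 to 9 reads in both libraries together. It was 53.8% (95% interval 53.5 to 54.1) in the 1461 regions with 50 to 199 reads, an odds ratio of 1.11 (95% interval 1.09 to 1.14; Fisher's exact test, adjusted p = 3.89e-29). In the 20 regions with 200 to 399 reads the share was 52.8% (95% interval 51.4 to 54.2), which did not differ detectably from that of the regions with 50 to 199 reads (odds ratio 0.96, 95% interval 0.91 to 1.02; adjusted p = 0.16). In the 8 regions with 400 or more reads the order turned: library 1 held 46.2% (95% interval 44.9 to 47.4), with an odds ratio of 0.74 (95% interval 0.70 to 0.77) against the regions with 50 to 199 reads (adjusted p = 1.36e-31). All 8 regions had a smaller share of library 1 than the 52.2% over all regions. The regions ranked next, with 398 and 279 reads, had shares of 46.5% and 45.9%, but they were singled out after their values were seen, and their class of 200 to 399 reads as a whole held the 52.8% given above. Within each class of total count, the spread of the splits around the class share lay inside the simulated range, for example 0.948 times binomial (range 0.916 to 1.086) at 50 to 99 reads and 1.076 times (range 0.858 to 1.153) at 100 to 199 reads.

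**Figure D2:**
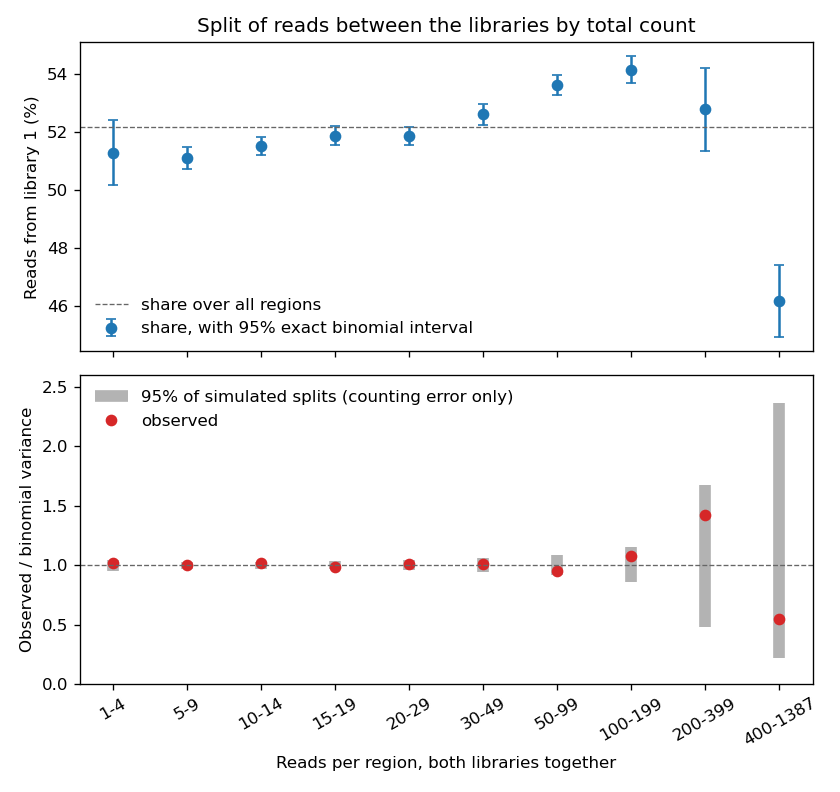
Upper panel, percentage of reads from library 1 (y axis) by class of reads per region in both libraries together (x axis), with exact 95% binomial intervals and the overall share dashed. The lower panel gives the observed variance of the split over its binomial value for the same classes, with grey bars for 95% of simulated splits; the share rises from 51.1% at 5 to 9 reads to 54.1% at 100 to 199 and is 46.2% at 400 or more.

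Region by region, 2 of 33586 regions differed between the libraries at an adjusted p under 0.05 (two-sided exact binomial test, Benjamini-Hochberg), both higher in library 2. Region 12073 had 331 reads in library 1 and 429 in library 2, a 1.41-fold difference after scaling to the library totals (95% interval 1.22 to 1.64; adjusted p = 0.044). Region 18076 had 527 and 637 reads, a 1.32-fold difference (95% interval 1.17 to 1.48; adjusted p = 0.044). Both are among the 8 regions with 400 or more reads, in all of which the share of library 1 was below 52.2%. Neither call held when the library share was set within each class of total count, where both adjusted p-values were 1. By construction that share comes from the same 8 regions and absorbs a difference common to them, so this loss is no evidence against the calls. Neither held with TMM scaling (adjusted p = 0.13 for both, exact binomial test), although the folds there were 1.40 (95% interval 1.21 to 1.62) and 1.30 (95% interval 1.16 to 1.46), nearly as large. Before adjustment 1129 regions (3.36%) had p under 0.05, where counting error alone gave 1098.5 on average. The test had little reach for sparse regions. A region needed at least 19 reads, all in 1 library, to pass a Bonferroni level as the only call, and 24910 regions (74.2% of those tested) had fewer.

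The 15 regions with the highest counts ranged from 246 reads in both libraries together to 1387, where the median region had 12. The highest region had 651 reads in library 1 and 736 in library 2. The 8 regions with 400 or more reads stood apart, from 532 reads upward, with the next region at 398. They held 1.09% of all reads. Among the 15, the share of library 1 ranged from 43.6% to 59.1%.

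Counts also varied with the order of the rows, in both libraries alike. In 3 long runs of consecutive rows the counts were about 0.45 to 0.47 times those of the stretch of rows before. The first run, of 521 rows (20112 to 20632), had a median of 3 reads per region in each library, against 6 in the 20111 rows before it. Its mean count was 0.448 times that of those rows (95% block bootstrap interval 0.409 to 0.493, which does not allow for the run having been picked by its low counts). The second run, of 105 rows (25835 to 25939), had a ratio of 0.458 (95% interval 0.361 to 0.559). The third, of 132 rows (33509 to 33640), ended 3 rows before the end of the table and had a ratio of 0.474 (95% interval 0.345 to 0.614). The stretches between the runs differed in their share of regions with high counts. In the first stretch, 627 of 20111 regions (3.12%, 95% interval 2.88 to 3.37) had 50 or more reads in both libraries together. In the second stretch 340 of 5202 did (6.54%, 95% interval 5.88 to 7.24), and in the third 514 of 7569 did (6.79%, 95% interval 6.23 to 7.38). The median of both libraries together was 12, 12 and 13 reads in these stretches. Neighbouring rows outside the runs had correlated counts (r = 0.15 across 32881 pairs of adjacent rows), and adjacent rows also correlated when one was read from library 1 and the next from library 2 (r = 0.13). Shuffled rows gave at most 0.011 for adjacent rows. Rows are not independent replicates, and the binomial intervals on these shares treat them as if they were.

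**Figure D3:**
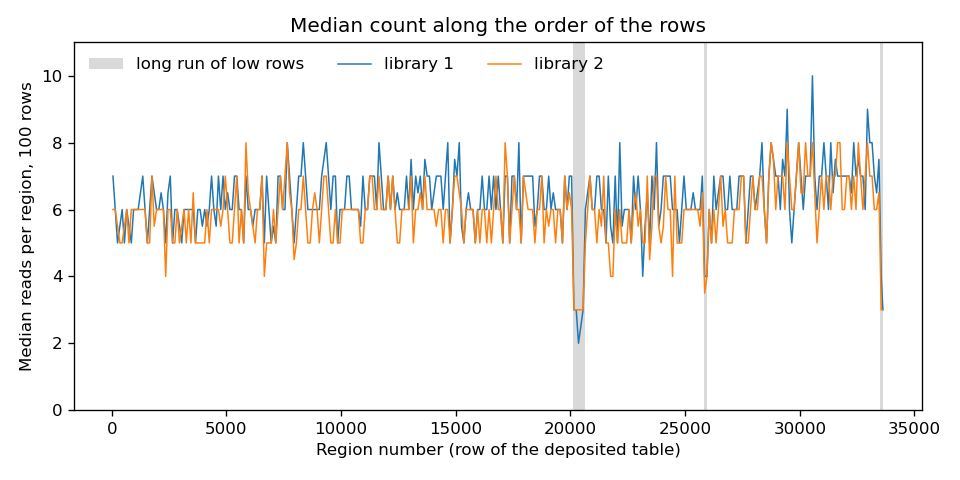
Median reads per region (y axis) in successive windows of 100 rows against the row number of the table (x axis), for library 1 and library 2. Grey bands mark the 3 long runs of low rows, in which both libraries fall together; window medians are 2 to 3 reads in windows wholly inside the first run, and 3.5 to 4 in the windows that cover the second run in part.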

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

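The overlap, the agreement and the count of differing regions were recomputed with other settings, one at a time; those described as added were chosen after seeing the data. The overlap moved with the definition of a detected region: 12310 regions were shared when each library kept the upper 50% of its regions, where independent lists would share 8411, 1315 at the added threshold of 4 times the median, and 1246 at that threshold with library 1 thinned to the depth of library 2 (added). Pearson's r was 0.602 with a pseudocount of 0.1, 0.786 with 5, and 0.669 with the filter on low counts (23958 regions kept). It was 0.704 without the regions of 200 or more reads and 0.705 without the long runs of low rows, both added. The 2 differing regions fell to 0 with TMM scaling. They fell to 0 at an adjusted p of 0.01, since both had an adjusted p of 0.044 in the main setting (exact binomial test). They also fell to 0 when the share of library 1 was set within each class of total count (added). By construction that setting absorbs a difference common to the 8 highest regions. For the other moves the cause was not tested. The same 2 regions were called with the filter on low counts and with the library share taken from regions under 200 reads (added). Over all settings the adjusted p of both regions ranged from 0.031 to 1. The alternatives on reciprocal overlap of regions, distance to genes, gene list matching and gene lists or genomic locations in each library alone were not run, because the row numbers were not tied to positions. No paired analysis was possible because there is only 1 group. Depth limits the comparison of single regions: 74.2% of tested regions had too few reads to pass, at any split, the Bonferroni level of a single call.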

Other observations

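All tests in this part were chosen after the results they address had been seen.

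The first pattern is the drift in the split of reads between the libraries with the total count. Counting error is argued against by a chi-square test of library by class of total count (p = 4.77e-57). A hypothesis for the regions of 5 to 199 reads is that library 2 held a larger share of background reads. Such reads may flatten its contrast between regions of low and of high count. The log odds of library 1 rose by 0.030 per doubling of the total count (95% interval 0.026 to 0.035), but this restates the drift the hypothesis was made for, so the hypothesis stays open. For the 8 regions of 400 or more reads, the odds ratio of library 1 against regions of 5 to 9 reads was 0.82 (95% interval 0.78 to 0.86). The same number of background reads in every region would give 1 or more, so the value argues against that form of the hypothesis there. Without widths or a control library, background that grows with the width of a region, or is gathered in these 8 regions, cannot be excluded. The edge at 400 reads is not a settled boundary: the 11 highest regions all lay under the overall share of 52.2%, a row noticed after the values were seen, while the class of 200 to 399 reads held 52.8%. What sets the highest regions apart stays open and was not tested, since their positions are not known, and no biological explanation was tested because both libraries are from 1 sample.

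The second pattern is the 3 long runs of rows with about 0.45 to 0.47 times the usual count. A chance order of rows is argued against, since the lowest run score was 42 and the highest of 1000 shuffles was 16. A fault of 1 library is argued against, since the ratio of the first run to the rows before it in library 1 was 0.949 times that in library 2 (95% interval 0.890 to 1.011). For the second run the value was 1.017 (95% interval 0.896 to 1.162), and for the third it was 1.057 (95% interval 0.947 to 1.179). The table, whose neighbouring rows correlate, may be 3 lists of regions placed end to end, each in genome order with the X chromosome last, in which case cells of a male would carry 1 copy of the X against 2 of each autosome and give a ratio near 0.5. The ratios of the runs were 0.448, 0.458 and 0.474, and narrower regions or a weaker mark could give the same values, alone or together with 1 copy of the X. Without coordinates these cannot be told apart.

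As a check on the bias of picking runs by their low counts, runs of the same lengths were planted at 0.5 times the counts of the rows before them. The search then returned median ratios of 0.495, 0.482 and 0.472 for the runs in their order (200 simulations each). For the first length 95% of the ratios lay from 0.453 to 0.577, just above the observed 0.448. For the second length they lay from 0.391 to 0.606, which holds the observed 0.458. For the third they lay from 0.376 to 0.576, which holds the observed 0.474. These simulations assume equal widths and mark in the run and the rows before it, which no table measures, so they decide nothing. Besides the long runs, 2 short runs of 55 and 29 rows scored 19 and 17, just above the highest shuffle.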
